A study of Mus musculus with 16 samples.

How the data were processed

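Total RNA was measured by RNA sequencing in 16 libraries of demyelinated mouse spinal cord. Lysolecithin, a detergent-like lipid that strips myelin from axons, was injected into the cord, and the lesion was cut from frozen tissue by laser microdissection, per the labels' protocols. The labels place the libraries in 4 groups of 4: mice housed with a free running wheel (exercise) or with a locked wheel (control), collected at day 5 or day 10. Within each group the libraries carry the numbers the labels give: control 1, 2, 5 and 6 and exercise 1, 2, 7 and 12 at day 5, and control 2, 3, 4 and 5 and exercise 13, 17, 18 and 19 at day 10. The labels do not state that each library comes from a separate animal, so p-values measure the spread between these libraries.

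Per the labels' protocols, RNA was extracted, amplified, selected for poly(A) and made into strand-specific libraries, which were sequenced on one machine type as single reads of 75 nt. Per the submitters' processing notes, reads were checked with FastQC 0.11.4 and aligned with TopHat2 2.0.10 and Bowtie 1.1.2 to GRCm38. The deposited table of raw counts per Ensembl gene was made with featureCounts 1.5.0-p1, counting reads on the gene's own strand, per the file headers. The authors also deposited a filtered table holding the same counts for 20076 of the 46078 genes. All 20076 were equal to the full table, and the genes the authors left out had at most 10 counts over the 16 libraries and together held 0.0124% of the reads. The deposited normalized signal equals the raw count divided by a size factor per library that ranged from 0.718 to 1.248. The authors' comparison tables give, per the file headers, log2 fold changes with standard errors, p-values and adjusted p-values for exercise against control at each day, in the layout of DESeq2, which the processing notes name in version 1.12.4. Their day 10 table lists 7 libraries and leaves out exercise replicate 17; the reason is not stated. The per-library log2 values in those tables and a file of variance-stabilised values were not used.

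Gene symbols and coordinates were taken from GENCODE mouse release 21 on GRCm38, which gave a symbol to 45143 of the 46078 gene IDs. Totals ran from 8.13 to 13.93 M counts per library. The mitochondrial ribosomal RNA gene mt-Rnr2 took 8.05% to 12.94% of them. As a check on sample identity, Xist lay between 123 and 322 CPM (counts scaled to the effective library size) in every library, and the Y-linked genes Ddx3y and Eif2s3y had 0 counts in all 16. Near-identical copies make the counts of ribosomal protein genes, Hspa1b and the pair Ly6c1 and Ly6c2 uncertain.

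The counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr on the 4 groups (minimum count 10, minimum total count 15), which left 15096. Libraries were scaled by TMM, and a quasi-likelihood model with 1 mean per group was fitted with robust estimation over all 16 libraries, so that the groups shared 1 estimate of spread with 12 residual degrees of freedom. The common biological coefficient of variation was 0.236. Exercise was compared with control at day 5, at day 10 and as the mean of both days, the difference between the days' exercise effects was tested as an interaction, and day 10 was compared with day 5 within control and within exercise. Adjusted p-values are Benjamini-Hochberg over the 15096 genes, with a threshold of 0.05. All other CPM values are TMM-scaled (counts scaled to the effective library size), given as mean ± SD over 4 libraries.

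The tests, the 32 gene lists, the rule for the genes named and most alternatives were fixed before the data were examined. The lists cover 15 cell types (oligodendrocyte precursors, mature oligodendrocytes and myelin, homeostatic microglia, monocyte-derived macrophages, neutrophils, lymphocytes, astrocytes, neurons, endothelium, mural cells, fibroblasts and meninges, Schwann cells, ependyma, erythrocytes and skeletal muscle), 15 processes (the PGC1a axis, oxidative phosphorylation, cholesterol synthesis, phagocytosis and lipid handling, proinflammatory mediators, reparative macrophages, reactive astrocytes, proliferation, interferon response, antigen presentation, immediate early genes, growth factors, inhibitory matrix, glycolysis and heat shock) and 2 quality measures (mitochondrially encoded and ribosomal protein genes). The 30 lists with at least 5 tested genes were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01. The erythrocyte list, with 2 tested genes, and the skeletal muscle list, with 4, were not tested. Camera with an estimated correlation and fry were the alternatives. Each list's level per library was its mean log2 CPM (prior count 2), compared by an exact two-sided permutation test over 70 arrangements of 4 against 4. The smallest possible p of this test is 0.0286. After Benjamini-Hochberg adjustment over the 30 lists, its smallest value in any comparison so tested was 0.0953, so that no list passed by it. At most 9 lists reached the smallest possible p in a comparison, and with so few none could pass after adjustment. This failure therefore says little of any single list.

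Named genes are, per comparison, up to 10 higher and 10 lower genes with the smallest p among those past the threshold, or the 5 per direction with the smallest p where none passed, which are said to have failed the correction. Predicted genes and pseudogenes were left out of these. In exercise against control, fixed genes were added (Ppargc1a, Mbp, Mog, Myrf, Olig2, Pdgfra, Gfap, Aif1, Cd68, Apoe, Igf1, Bdnf, Mki67 and Snap25). Up to 4 members with the smallest p of each list described, and the 5 genes per direction with the smallest adjusted p in each of the authors' tables, complete the rule. A gene counts under every part that names it. Some genes that the rule names are not reported here.

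The pipeline was tested on simulated data in which a seeded set of genes was changed by known factors. Of the changed genes tested in the simulated day 5 comparison (14883 genes), 26.9% were called at a 1.5-fold change, 57.6% at 2-fold and 84.8% at 4-fold, and 5 of 14668 unchanged genes were called. In the simulated day 10 comparison (14888 genes), the shares were 22.7%, 52.2% and 77.3%, and 9 of 14673 unchanged genes were called. Genes were simulated independently, with the same spread in every group and no deviation shared by the genes of a library. These shares therefore need not hold for the real libraries.

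Alternatives were RLE and upper-quartile scaling, no low-count filter, a filter of at least 50 counts in at least 4 libraries, a fit without robust estimation, limma-voom with sample quality weights, DESeq2 1.42.0, a fit on the 8 libraries of a contrast alone, the replicate number as a block, and leaving out each library in turn. Added after the data were seen were DESeq2 on the 8 libraries of a contrast, DESeq2 on the 7 libraries of the authors' day 10 table, leaving out mt-Rnr2, and the neuron list as a covariate. Under TMM, RLE, upper-quartile scaling and without mt-Rnr2, the median log2 fold change of all genes moved no further from 0 than 0.018 in any comparison.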

Results

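Gene expression was measured in lysolecithin-demyelinated lesions of mouse spinal cord from mice with a free running wheel (exercise) or a locked one (control), 5 or 10 days into the experiment, with 4 libraries in each of the 4 groups. The series title names remyelination, exercise and oligodendroglial PGC1a (encoded by Ppargc1a), and the comparisons below ask how running changed the lesion at each day and how the lesion changed between the days. Totals were 11.2 to 13.93 M counts (M, mega) in control and 8.13 to 10.93 M in exercise at day 5, so that every exercise library was shallower than every control library. At day 10 they were 10.71 to 12.7 M in control and 9.77 to 11.09 M in exercise. The share of counts in mt-Rnr2 also separated the day 5 groups, at 8.05% to 10.28% in control and 10.91% to 12.94% in exercise, and overlapped at day 10 (8.81% to 12.61% and 8.51% to 12.32%). In a multidimensional scaling of the 16 libraries, the first dimension held 21.7% of the variance and separated day 5 from day 10. On the second dimension (10.7%), exercise replicate 17 at day 10 lay farthest from 0, at 1.241, and the day 5 control libraries lay above the day 5 exercise libraries, which groups of 4 and 4 do by chance in 2.86% of arrangements.

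**Figure D1:**
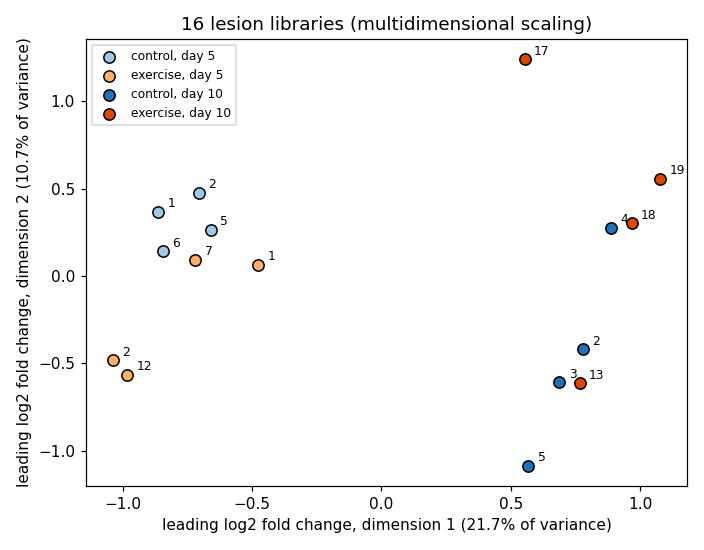
Multidimensional scaling of the 16 libraries on log2 CPM, with the first dimension (21.7% of the variance) on the x axis, the second (10.7%) on the y axis, 1 point per library in the colour of its group and the library's number beside it. All 8 day 5 libraries lie left of 0 and all 8 day 10 libraries right of it, and on the second dimension the day 5 control libraries (0.142 to 0.475) lie above the day 5 exercise libraries (-0.567 to 0.094), while the groups of day 10 overlap.

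In lesions of control mice, day 10 differed from day 5 by a fall of cell-cycle genes and a rise of myelin genes, which answers how the untreated lesion moves on. Proliferation genes dropped as a group: all 23 listed genes were lower, and 22 passed the threshold. By camera with its preset correlation, genes of mature oligodendrocytes and myelin, of astrocytes, of fibroblasts and meninges and of homeostatic microglia were higher, while genes of phagocytosis and lipid handling and of reparative macrophages were lower. Of these lists only proliferation also passed with an estimated correlation. Igf2 and Ppargc1a were also higher at day 10. Rrm2 (ENSMUSG00000020649, chromosome 12, 24708241 to 24714146) fell from 57.5 ± 1.95 to 14.1 ± 4.23 CPM (SD, n = 4; log2 fold change -2.03, SE 0.19, adjusted p 2.18e-05 by edgeR's quasi-likelihood test). Ccnb2 (-2.02), Ube2c (-2.21), Cdca3 (-2.20), Ckap2l (-1.81), Kpna2 (-1.31), Mcm6 (-1.19), Exosc9 (-1.13) and H2afz (-0.94) were the other cell-cycle and nuclear genes among the 10 lower genes with the smallest p, and Serpina3n, a gene of reactive astrocytes, was the remaining one (-1.37, from 581 ± 89.8 to 225 ± 35.2 CPM). Among the higher genes, Tspan2 (ENSMUSG00000027858, chromosome 3, 102734529 to 102801513) rose 5.15-fold, from 177 ± 21.2 to 909 ± 131 CPM, and Opalin rose 3.8-fold, from 24.6 ± 1.61 to 93.7 ± 9.81 CPM. Mbp rose from 5113 ± 871 to 9526 ± 496 CPM (log2 0.90, adjusted p 0.00444) and Plekhb1 by 0.76. Lag3 (ENSMUSG00000030124, chromosome 6, 124904361 to 124911705) rose from 1.13 ± 0.549 to 14.3 ± 2.11 CPM, and Vtn rose 4.45-fold from 25 ± 5.43 to 111 ± 16.3 CPM. Cd83, Tagap, Plekha1, Spata13, Prickle1 and Ifngr1, at 1.65-fold to 3.1-fold, completed the 10. Igf2 rose from 126 ± 81.9 to 1564 ± 274 CPM (log2 3.64, SE 0.59, adjusted p 0.00117). Ppargc1a rose from 4.31 ± 1.04 to 9.99 ± 2.42 CPM (log2 1.21, SE 0.28, adjusted p 0.00783). Apoe rose from 7127 ± 939 to 13780 ± 660.0 CPM, while the scavenger-receptor and lipid-droplet genes Cd36 (-2.50), Msr1 (-1.84) and Plin2 (-1.48) and the reparative macrophage genes Arg1 (-3.27), Chil3 (-2.17), Cd200r1 (-1.17) and Stab1 (-0.96) fell. The microglial genes Csf1r (0.74), Siglech (from 19.2 ± 9.7 to 54.4 ± 11.5 CPM), Sall1 (0.85) and Sparc (0.64), the astrocyte genes Aqp4 (1.03), Agt (1.45), Ntsr2 (1.54) and Slc1a3 (0.60), and Erbb3 (1.75) and Serping1 (1.55) rose.

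By edgeR, 1858 of 15096 genes passed an adjusted p of 0.05 in this comparison, 855 higher and 1003 lower, and 4056 had an unadjusted p under 0.05 against 755 expected by chance. Camera called 13 of the 30 lists, and fry called 9, of which 5 were higher and 4 lower. The proliferation list was lower in all 23 genes (median log2 -1.73, adjusted p 1.01e-47; its level fell from 5.38 ± 0.02 to 3.73 ± 0.18 log2 CPM), with 22 genes lower over all genes tested and 23 adjusted over the list alone. It alone also passed camera with an estimated correlation (adjusted p 0.0236). The other 12 lists called by camera did not pass with an estimated correlation. Higher were mature oligodendrocytes and myelin (median 0.67; 10 higher and 1 lower, 16 and 1 adjusted over the list alone), homeostatic microglia (0.64; 6 and 8 higher), astrocytes (0.58; 7 and 12 higher), fibroblasts and meninges (0.91; 4 and 4 higher) and Schwann cells (0.88; 3 and 6 higher). Lower were monocyte-derived macrophages (-0.50), phagocytosis and lipid handling (-0.49; 3 genes higher and 13 lower), reparative macrophages (-0.74), interferon response (-0.89, with 0 of 21 genes called and all 21 lower), glycolysis (-0.48), oxidative phosphorylation (-0.17) and heat shock (-0.22).

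In lesions of exercise mice, cell-cycle genes fell from day 5 to day 10, as did the lipid-handling genes Cd36, Plin2 and Fabp5, and homeostatic microglial genes and some myelin genes rose. By camera with its preset correlation, the interferon, endothelial, neuronal, cholesterol synthesis and oxidative phosphorylation lists were lower at day 10, with a minority of members past the threshold in all but interferon response. No list passed with an estimated correlation when all libraries were used. Rrm2 (-1.45), Ccnb2 (-1.47), Mcm6 (-1.05), Kpna2 (-1.05), Hmgb2 (-1.03) and Ccnb1 (-1.80) fell. Cd36 fell from 345 ± 129.8 to 47.6 ± 25.9 CPM (log2 -2.86, SE 0.37, adjusted p 0.000321 by edgeR), and Plin2 (-1.47), Fabp5 (-1.19), Lgals1 (-1.81) and Cd24a (-1.89) were the other lower genes with the smallest p. Csf1r (ENSMUSG00000024621, chromosome 18, 61105572 to 61132149) rose from 364 ± 52.6 to 732 ± 49.8 CPM (log2 1.01, SE 0.11, adjusted p 5.23e-05). Siglech rose from 15.8 ± 4.84 to 89.6 ± 18.7 CPM, Sall1 from 29.1 ± 4.97 to 72 ± 10.8 CPM, and Mertk from 94.3 ± 4.65 to 187 ± 14.5 CPM. Spata13 (1.27), Plekha1 (1.25), Tgfbr1 (1.20), Smap2 (1.14), Ifngr1 (0.81), Cd83 (0.91), Csf3r (1.29) and Lag3 (3.34) were the other higher genes with the smallest p. Tspan2 (1.75) and Opalin (1.40) rose, and Cnp (0.68) and Mog (0.78) passed the threshold with all libraries and lost it when any of exercise replicates 2, 7 or 12 at day 5 or 13 or 18 at day 10 was left out. The interferon genes Rtp4 (-2.11) and Oasl2 (-1.97), the endothelial genes Emcn (-1.22) and Pecam1 (-1.02), and the neuronal genes Stmn2 (-1.74), Tubb3 (-0.92), Uchl1 (-0.95) and Chat (-1.84) fell. Arg1 (-3.03), Chil3 (-3.53) and Stab1 (-0.62) fell, as did Idi1 (-0.76), Msmo1 (-0.56) and Fdft1 (-0.61) of cholesterol synthesis.

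EdgeR called 1520 genes in this comparison, 781 higher and 739 lower, with 3899 at an unadjusted p under 0.05. Without exercise replicate 7 at day 5 the count was 975. Camera called 13 lists, none of which passed with an estimated correlation; without exercise replicate 17 of day 10, proliferation did (adjusted p 0.00492, 22 of 23 lower, median -1.51), and camera also called phagocytosis and lipid handling (2.05e-05) and glycolysis (0.00151). The nearest were proliferation (median -1.17; 20 of 23 lower, 23 adjusted over the list alone) and homeostatic microglia (0.93; 12 of 16 higher, 14 adjusted over the list alone; level 6.67 ± 0.32 to 7.74 ± 0.34), both at an adjusted p of 0.0962. Lower were also interferon response (-1.34; 12 lower, 15 adjusted over the list alone), monocyte-derived macrophages (-0.81), endothelium (-0.46), neurons (-0.94), cholesterol synthesis (-0.39), oxidative phosphorylation (-0.33), reparative macrophages (-0.59) and reactive astrocytes (-0.30). Mature oligodendrocytes and myelin (0.26; 4 higher, 5 adjusted over the list alone), fibroblasts and meninges (0.63) and ribosomal protein genes (0.20) were higher. Fry called 11 lists, 1 higher and 10 lower. The myelin list did not pass without exercise replicate 13 (adjusted p 0.164) or 18 (0.187) of day 10, and without replicate 17 it had 10 genes higher, as in control, with a median of 0.47 (4.17e-09). The interferon list had 5 genes lower without replicate 17. The fibroblast list did not pass without 18 (0.308) or 19 (0.102), nor the ribosomal list without 17 (0.352). Across the 15096 genes, which are not independent replicates, the day effects in control and exercise had a Pearson correlation of 0.504 and a Spearman correlation of 0.493 and share no libraries. Both comparisons called 332 genes higher, against 44.2 for independent lists, and 401 lower, against 49.1.

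**Figure D2:**
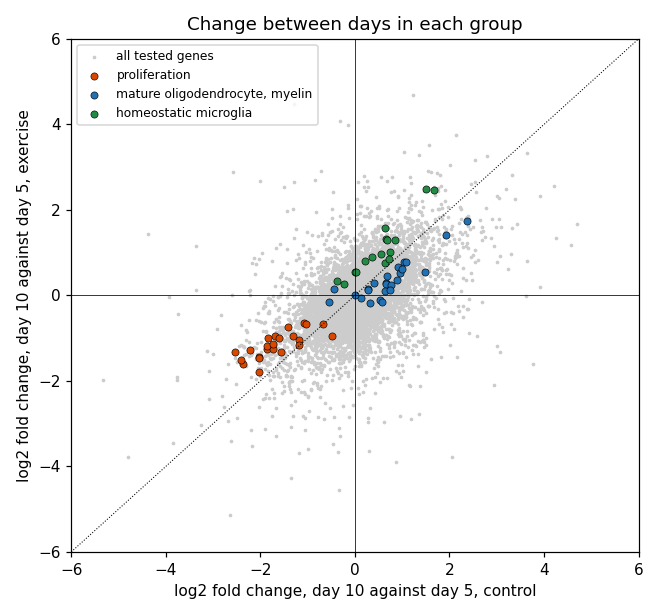
Log2 fold change of each tested gene from day 5 to day 10 in control (x axis) and in exercise (y axis), with the proliferation list in orange, mature oligodendrocytes and myelin in blue and homeostatic microglia in green; 5 genes lie outside the range drawn. All 23 proliferation genes are below 0 in both comparisons, and all 16 microglial genes are above 0 in exercise.

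At day 5, no gene differed between exercise and control lesions past the threshold by edgeR, which bears on whether running had changed the lesion by that day but does not show that it had not. The nearest genes were Prune2, Pdpn, Acox3, mt-Nd5 and Pi4ka, higher with exercise, and Ipo11, Selenos, Bin3, Sec61b and Tmem18, lower, and all failed the correction. Neuronal and mitochondrially encoded genes were mostly higher with exercise, and ribosomal protein genes mostly lower, by camera with its preset correlation, and none of these lists passed with an estimated correlation. Ppargc1a, the gene of PGC1a, was 1.75-fold higher on average and did not pass. Prune2 (ENSMUSG00000039126, chromosome 19, 16956118 to 17223932) had 42.2 ± 2.03 CPM in control and 70.2 ± 12.4 in exercise (SD, n = 4; log2 0.73, SE 0.12, adjusted p 0.147). Ipo11 had 275 ± 30.7 and 193 ± 8.18 CPM (log2 -0.52, SE 0.09, adjusted p 0.147). Pdpn (0.81), Acox3 (0.53), Selenos (-0.52), Bin3 (-0.64) and Sec61b (-0.76) had an adjusted p of 0.212, and mt-Nd5 (0.71), Pi4ka (0.51) and Tmem18 (-0.49) one of 0.234. Ppargc1a (ENSMUSG00000029167, chromosome 5, 51454250 to 51567726) had 4.31 ± 1.04 CPM in control and 7.59 ± 1.98 in exercise (log2 0.81, SE 0.28, adjusted p 0.37). The oligodendrocyte genes Mbp (0.22), Mog (-0.23), Myrf (0.39), Olig2 (-0.34) and Pdgfra (-0.27) had adjusted p-values between 0.447 for Olig2 and 0.771 for Mog. Gfap (0.20), Aif1 (-0.33), Cd68 (0.10), Apoe (0.07), Igf1 (-0.18), Bdnf (0.72), Mki67 (0.40) and Snap25 (0.82) did not pass either. In the authors' deposited table for day 5, the 5 higher genes with the smallest adjusted p were Ret (log2 1.28), Adam11 (1.29), Nefm (1.55), Uts2 (1.90) and Kif21a (0.83), and the 5 lower ones were Tmem189 (-0.49), Tcea1 (-0.54), Scand1 (-2.77), Rps15 (-0.54) and Gpn3 (-0.96). In edgeR's fit, Ret had 16.4 ± 4.06 CPM in control and 39.9 ± 6.83 in exercise, with an adjusted p of 0.268.

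EdgeR called 0 genes at day 5, while 1513 of 15096 had an unadjusted p under 0.05; limma-voom called 0, DESeq2 called 79 genes on all 16 libraries and 259 on the 8 libraries of day 5, and the authors' deposited table holds 271. All 271 had the same sign in edgeR's fit, and 248 of them had an unadjusted p under 0.05 there. Camera called 3 lists. Regrouping the same 8 libraries in other ways gave a median of 8.5 lists, so that calls at the preset correlation do not by themselves show an effect of exercise. The groups of day 5 were also separated in depth and mt-Rnr2 share, which cannot be told apart from exercise here. Neurons were higher in 21 of 24 genes (median 0.65, adjusted p 3.4e-05; Chat 1.21, Nefm 1.56, Stmn2 0.61, and Tac1 lower at -2.15), with 0 genes called over all genes and 0 adjusted over the list alone. Mitochondrially encoded genes were higher in 8 of 9 (median 0.35, adjusted p 3.4e-05; mt-Nd5 0.71, mt-Atp8 0.93, mt-Cytb 0.42 and mt-Nd1 0.30), with 3 genes higher adjusted over the list alone. Ribosomal protein genes were lower in 52 of 67 (median -0.12, adjusted p 0.000177; Rps15 -0.53, Rpl36 -0.54, Rpl24 -0.88 and Rps14 -0.44). With an estimated correlation all 3 had an adjusted p of 0.986. The ribosomal list did not pass without control replicate 6 (0.461), and without control replicate 5 there were 5 lists. Among the 27 lists that did not pass were PGC1a axis (median 0.08), oligodendrocyte precursors (-0.15), mature oligodendrocytes and myelin (0.07), astrocytes (0.01), endothelium (-0.04) and heat shock (-0.07; 1 gene, Xbp1 at -0.54, lower adjusted over the list alone).

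At day 10, 29 genes differed between exercise and control lesions, in calls that depended on single libraries, and endothelial genes were lower as a list. This bears on whether running had changed the lesion by then. Fkbp5, Mertk, C5ar1, Alox5, Itgam, H2-DMa, Dock2 and Tnfrsf11a were higher with exercise. Igf2, Igfbp4, Slco1a4, Cxcl12, Vcam1, Vtn and Adh1 were lower. None of the fixed genes, Ppargc1a and Mbp among them, passed. Fkbp5 (ENSMUSG00000024222, chromosome 17, 28399095 to 28517524) rose 2.07-fold, from 106 ± 24.9 CPM in control to 219.8 ± 26.5 in exercise (SD, n = 4; log2 1.05, SE 0.16, adjusted p 0.0374). Mertk (ENSMUSG00000014361, chromosome 2, 128698956 to 128802894) rose from 123 ± 11.4 to 187 ± 14.5 CPM, C5ar1 (ENSMUSG00000049130, chromosome 7, 16246743 to 16259540) from 77.4 ± 12 to 137 ± 20.7, and Dock2 from 72.8 ± 6.1 to 116 ± 14.4. Alox5 rose 2.39-fold from 6.24 ± 1.42 CPM, H2-DMa 2.19-fold from 25.9 ± 6.8 and Itgam 2.03-fold from 59.4 ± 9.75. Ankrd27 (log2 0.96), Apbb1ip (0.89), Tnfrsf11a (0.72) and Pacsin2 (0.57) were the other higher genes with the smallest p. Igf2 (ENSMUSG00000048583, chromosome 7, 142650766 to 142666816) was 8.22-fold lower, with 1564 ± 274 CPM in control and 190.3 ± 125 in exercise (log2 -3.04, SE 0.58, adjusted p 0.048), and each exercise library lay below each control library. Igfbp4 (ENSMUSG00000017493, chromosome 11, 99041244 to 99054392) fell from 142 ± 21 to 73.2 ± 9.42 CPM, Slco1a4 (ENSMUSG00000030237, chromosome 6, 141805440 to 141856199) from 101 ± 15.1 to 55.6 ± 14.9, Cxcl12 from 69.8 ± 8.41 to 33.5 ± 7.44, Vcam1 from 61.5 ± 3.69 to 38.4 ± 3.17 and Vtn from 111 ± 16.3 to 50.8 ± 17.8. Igsf1 fell from 49.8 ± 16.7 to 14.6 ± 4.02 CPM, Plac8 from 17.6 ± 3.71 to 4.45 ± 2.48 and Adh1 from 5.37 ± 2.88 to 0.435 ± 0.268, and Dbi (-0.80), Ppm1l (-0.72) and Cox6c (-0.62) were the other lower genes with the smallest p.

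Ppargc1a had 9.99 ± 2.42 CPM in control and 6.4 ± 2.07 in exercise at day 10 (SD, n = 4; log2 -0.64, SE 0.27, adjusted p 0.339 by edgeR). Mbp had 9526 ± 496 and 7574 ± 2384 CPM (log2 -0.33, adjusted p 0.475). Mog (-0.48), Myrf (0.01), Olig2 (-0.37), Pdgfra (-0.09), Gfap (-0.17), Aif1 (0.25), Cd68 (0.31), Apoe (-0.09), Igf1 (-0.17), Bdnf (-1.52) and Snap25 (-0.39) did not pass. Mki67 had 13 ± 1.24 CPM in control and 25.9 ± 11.2 in exercise (log2 0.99, adjusted p 0.12). Just outside the threshold were the endothelial Cldn5 (-1.03, adjusted p 0.0544), Ccl7 (-1.67, 0.0613), Cp (-0.88, 0.0644), the astrocyte gap junction gene Gja1 (-0.76, 0.0713), Serpina3n (0.67, 0.0761) and Ly6c1 (-0.74, 0.0824).

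EdgeR called 29 genes at day 10, 16 higher and 13 lower, with adjusted p-values between 0.0374 and 0.05, and 1935 genes had an unadjusted p under 0.05. The fit shared 1 estimate of spread over the 4 groups, although the day 10 exercise libraries were less alike. Their pairs had Pearson correlations of 0.9586 to 0.9734, against 0.9725 to 0.9808 in day 10 control. On the 8 libraries of day 10 alone edgeR called 0 genes. That fit also had fewer residual degrees of freedom, so these reasons cannot be told apart. The calls depended on single libraries: 0 genes passed without control replicate 2, control replicate 3, exercise replicate 17 or exercise replicate 19, 2 without control replicate 5, 1 without exercise replicate 13, 19 without control replicate 4 and 133 without exercise replicate 18. The authors' deposited table, which leaves out exercise replicate 17, holds 179 genes, of which 175 were tested here and had the same sign; all 29 genes called by edgeR are among them. Its 5 higher genes with the smallest adjusted p were Fbxo40 (log2 2.37), Epha3 (1.96), Fkbp5 (0.95), C5ar1 (0.84) and Ivns1abp (0.42), and its 5 lower ones were Igf2 (-2.71), Ackr1 (-1.49), Igsf1 (-1.63), Ccl7 (-1.64) and Slc38a5 (-1.69). DESeq2 called 218 genes on all 16 libraries.

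**Figure D3:**
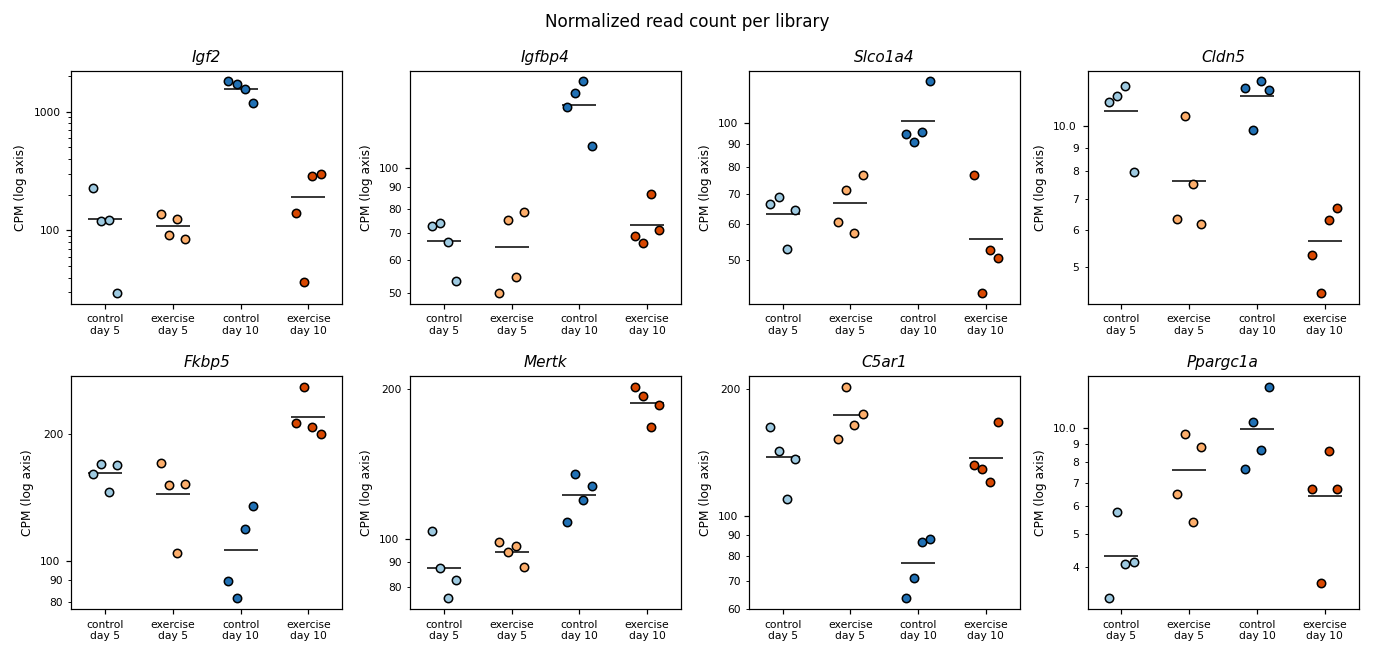
Normalized read count (CPM, log y axis) of Igf2, Igfbp4, Slco1a4, Cldn5, Fkbp5, Mertk, C5ar1 and Ppargc1a per library in the 4 groups, with a bar at each group's mean. At day 10 all 4 exercise libraries lie below all 4 control libraries for Igf2, Igfbp4, Slco1a4 and Cldn5 and above them for Fkbp5, Mertk and C5ar1.

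Of the gene lists at day 10, endothelium was the only one past the threshold in camera, in camera with an estimated correlation and in fry. It was lower with exercise in 13 of 16 genes, with Slco1a4, Cldn5, Ly6c1 and Esam (-0.77) at the smallest p, and mural cell genes were lower in 10 of 10, with Vtn and Kcnj8 (-1.37). Homeostatic microglial genes were higher in 15 of 16, with Csf1r (0.40), Fcrls (0.63), Olfml3 (0.49) and Selplg (0.55). Myelin genes were lower in 22 of 25, with Cnp (-0.48), Opalin (-0.48) and Plekhb1 (-0.35), and astrocyte genes in 16 of 18, with Gja1, Gjb6 (-0.77), Mlc1 (-0.71) and Aqp4 (-0.43). The endothelial list had a median of -0.60 (camera adjusted p 1.03e-06, 0.0172 with an estimated correlation; fry 0.00157), and its level was 4.33 ± 0.12 log2 CPM in control and 3.85 ± 0.15 in exercise (SD, n = 4; exact p 0.0286). It had 1 gene lower over all genes tested, and 1 higher and 7 lower adjusted over the list alone; without exercise replicate 17 its adjusted p with an estimated correlation was 0.0223. Camera called 14 lists, 4 higher and 10 lower, of which the other 13 did not pass with an estimated correlation. Schwann cells (median -1.03), mural cells (-0.34), mature oligodendrocytes and myelin (-0.33), astrocytes (-0.36), cholesterol synthesis (-0.28), oxidative phosphorylation (-0.11), fibroblasts and meninges (-0.15), interferon response (-0.44) and neurons (-0.15) were lower, and homeostatic microglia (0.48), proliferation (0.44), glycolysis (0.33) and phagocytosis and lipid handling (0.24) were higher. Without exercise replicate 17, camera did not call myelin (adjusted p 0.064), proliferation (0.192), glycolysis (0.0772), phagocytosis and lipid handling (0.788) or neurons (0.911), and the medians of phagocytosis and lipid handling (-0.02), neurons (0.04) and fibroblasts and meninges (0.09) changed sign. It then also called monocyte-derived macrophages (lower, 0.0348) and ribosomal protein genes (lower, 0.0248, with a median of -0.07). Neurons also failed without control replicate 2, 3 or 5 or exercise replicate 18 or 19, interferon response without control replicate 2 (0.531) or exercise replicate 13 (0.104), and fibroblasts and meninges without exercise replicate 13 (0.0837).

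The other 16 lists did not pass at day 10 with all libraries. Their medians were -0.11 for oligodendrocyte precursors, -0.25 for monocyte-derived macrophages (Itgam 1 higher and Plac8 1 lower), -1.71 for neutrophils, 0.09 for lymphocytes, -0.37 for ependyma, -0.09 for the PGC1a axis, 0.18 for proinflammatory mediators, 0.14 for reparative macrophages, -0.12 for reactive astrocytes, 0.08 for antigen presentation, -0.11 for immediate early genes, -0.09 for growth factors, -0.14 for inhibitory matrix, 0.07 for heat shock, 0.03 for mitochondrially encoded genes and 0.04 for ribosomal protein genes. Within the PGC1a axis, Vegfa (0.74), Nrf1 (0.48), Tfb1m (-0.37) and Ppargc1a itself had the smallest p, and 1 gene was higher adjusted over the list alone.

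**Figure D4:**
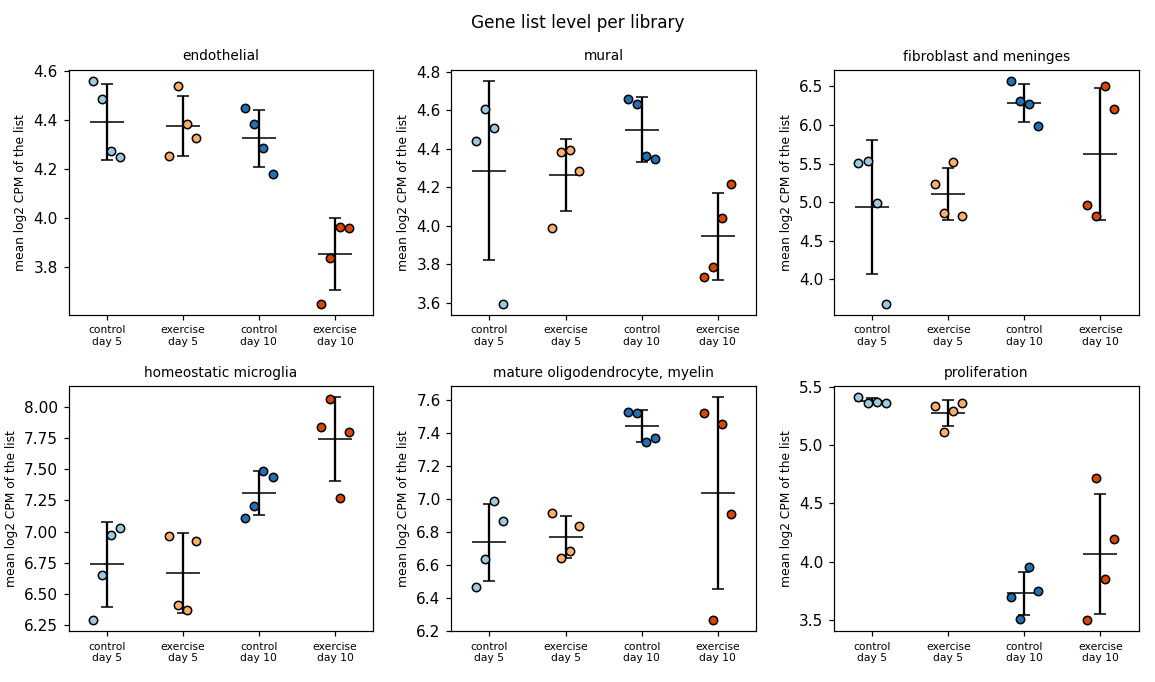
Mean log2 CPM of the endothelial, mural, fibroblast and meninges, homeostatic microglia, mature oligodendrocyte and myelin, and proliferation lists per library in the 4 groups, with each group's mean ± SD (n = 4). The 4 exercise libraries of day 10 lie below the 4 control libraries for the endothelial and mural lists. Exercise replicate 17 is the lowest library of its group in the myelin list and the highest in the proliferation list.

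Averaged over both days, exercise lesions had more RNA of Prune2, Kdm5c, Rassf2, C5ar1, Arid1b, Zfp180, Alox5, Acox3, Dock2 and Kif21b and less of Dbi, Sf3b6, Cox6c, Lmo4, Akap17b, Gpn3, Cdh10, Ipo11 and Cldn5. This answers which genes differed on average over the days, and such a call is not a call at each day: Ipo11 was at -0.52 at day 5 and -0.15 at day 10, and Dock2 at 0.15 and 0.68. Dbi (ENSMUSG00000026385, chromosome 1, 120113280 to 120121078), which encodes the acyl-CoA binding protein, went from 80.3 ± 11.9 to 58.5 ± 4.63 CPM at day 5 and from 101 ± 8.48 to 57.8 ± 9.81 at day 10 (averaged log2 -0.63, SE 0.09, adjusted p 0.0241). Prune2 (0.53) and Kdm5c (0.52), and Sf3b6 (-0.36), Cox6c (-0.52) and Lmo4 (-0.56), had the same adjusted p of 0.0241. Kdm5c had 22.5 ± 2.37 and 31.2 ± 1.81 CPM at day 5 and 24.7 ± 1.18 and 36.6 ± 4.87 at day 10 in control and exercise. Arid1b (0.85), Alox5 (0.84), Zfp180 (0.64), C5ar1 (0.58), Kif21b (0.49), Dock2 (0.41), Acox3 (0.40) and Rassf2 (0.40) rose, and Gpn3 (-0.77), Akap17b (-0.75), Cdh10 (-0.57) and Ipo11 (-0.34) fell. Cldn5 (ENSMUSG00000041378, chromosome 16, 18776847 to 18778260), the endothelial tight-junction gene, fell by 0.77 on the log2 scale (adjusted p 0.0484). Of the fixed genes, Mki67 (0.69, adjusted p 0.0931) and Olig2 (-0.35, 0.126) came nearest. Ppargc1a was at 0.09, Mbp at -0.06, Mog at -0.35, Myrf at 0.20, Pdgfra at -0.18, Gfap at 0.02, Aif1 at -0.04, Cd68 at 0.21, Apoe at -0.01, Igf1 at -0.18, Bdnf at -0.40 and Snap25 at 0.21.

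EdgeR called 22 genes in the average, 13 higher and 9 lower, and 2053 had an unadjusted p under 0.05. No gene passed without control replicate 5 of day 5, control replicate 5 of day 10, or exercise replicate 13 or 19 of day 10. The count was 1 without control replicate 2 or exercise replicate 7 of day 5, 2 without exercise replicate 12, 9 without exercise replicate 1 and 11 without control replicate 1 of day 5, 4 without control replicate 2 and 4 without control replicate 3 of day 10, 80 without exercise replicate 17 and 100 without exercise replicate 18. The 13 higher genes had a median exon length of 7110 nt and the 9 lower ones of 3530 nt, against 3815 nt for all genes tested. Exon length is the length that featureCounts gives per gene, over all its annotated exons. Camera called 12 lists, and none passed with an estimated correlation. Lower were endothelium (median -0.24; adjusted p 0.000411, 0.102 with an estimated correlation; 1 gene lower, 6 adjusted over the list alone), Schwann cells (-0.46), mature oligodendrocytes and myelin (-0.10), astrocytes (-0.18), mural cells (-0.17), cholesterol synthesis (-0.12), oxidative phosphorylation (-0.04) and interferon response (-0.18), and higher were homeostatic microglia (0.21), glycolysis (0.17), mitochondrially encoded genes (0.17) and proliferation (0.15). Only 6 lists passed without exercise replicate 17 of day 10, where the proliferation median was -0.01, and 7 without exercise replicate 12 of day 5. Of the lists named, endothelium, Schwann cells, oxidative phosphorylation and mitochondrially encoded genes stayed without replicate 17. Neurons (higher, camera adjusted p 0.0126) and ribosomal protein genes (lower, 0.000103) passed only then.

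The exercise effects of the days were then compared with each other, which answers whether running acted differently at day 5 and day 10. Fkbp5, Acer3, Pag1, Tars2 and Ssh2 had the smallest p among genes with a higher exercise effect at day 10, and Vcam1, Hebp2, Adh1 and Lcn2 among those with a lower one, and all failed the correction. Fkbp5 had an interaction of 1.21 (log2, SE 0.22) and Vcam1 of -0.91 (SE 0.17), both at an adjusted p of 0.296 by edgeR, and the other 7 were at 0.4. Lcn2, with an interaction of -2.54, had 12.1 ± 4.04 and 24.4 ± 12.9 CPM in control and exercise at day 5 and 18.3 ± 3.73 and 6.37 ± 1.94 at day 10 (SD, n = 4). Ppargc1a, 1.75-fold higher with exercise at day 5 and 1.56-fold lower at day 10, had an interaction of -1.45 and an adjusted p of 0.422. EdgeR called 0 genes, with 1376 at an unadjusted p under 0.05, limma-voom called 0 and DESeq2 called 13. Camera called 18 lists, 5 higher and 13 lower, and 11 without exercise replicate 17; none passed with an estimated correlation. Across the 15096 genes, which are not independent replicates, the exercise effects at day 5 and day 10 had a Pearson correlation of 0.0431 and a Spearman correlation of 0.0842 (covariance 0.00821), and 53.5% of genes had the same sign. The Pearson correlation was -0.0312 without exercise replicate 13 of day 10, -0.00493 without exercise replicate 1 of day 5 and 0.107 without exercise replicate 17 of day 10.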

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

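The splits behind every count of genes and behind the correlation between days, the tests of exercise replicate 17 alone and of meningeal tissue for the endothelial list, and the depth test of replicate 17 were chosen only after the result was seen. In the 4 groups, 348 values (total counts, mt-Rnr2 shares, list levels and named genes) were searched for a single library far from its group by Dixon's test, and 17 were found, against 17.4 that chance gives at 1 in 20. At day 5 these were, with the range of the other libraries of the group, the mural list in control replicate 6 (3.6; 4.44 to 4.61), the proliferation list in control replicate 1 (5.41; 5.36 to 5.37), and Myrf in control replicate 6 (37.8 CPM; 28.1 to 29.4). Vcam1 (47.7; 52.7 to 53.2) and Gpn3 (38; 27.8 to 28.7) in control replicate 5, Dbi in exercise replicate 2 (65.4; 55.5 to 56.9) and Plac8 in exercise replicate 1 (4.06; 11.4 to 12.2) were the others of that day.

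At day 10 they were Cd68 in control replicate 2 (465 CPM; the others 620 to 635), Slco1a4 in control replicate 5 (124; 90.9 to 95.8) and Igsf1 in control replicate 3 (74.7; 38.6 to 43.2). Exercise replicate 13 held 4 of them: the monocyte-derived macrophage list (4.65; 4.94 to 4.99), the mitochondrially encoded list (6.46; 5.96 to 6.01), mt-Nd5 (129; 80.6 to 83.9) and Snap25 (221; 26.3 to 49.4). The glycolysis list in exercise replicate 17 (7.45; 6.93 to 6.94), Ankrd27 in exercise replicate 19 (35.7; 20.7 to 20.9) and Cxcl12 in exercise replicate 18 (44.6; 29.4 to 30.2) complete the set. In Slco1a4 and Igsf1, called lower at day 10, in Ankrd27, called higher, and in Gpn3, called lower in the average over days, the far library enlarges the called difference. In Cxcl12, called lower at day 10, it reduces the difference, as it does in Dbi for the average.

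The exercise effect differed between the days in 18 lists by camera's test of the interaction. The difference (median log2, day 10 minus day 5) was positive for homeostatic microglia (0.542, higher in 16 of 16 genes), proliferation (0.584), glycolysis (0.29), phagocytosis and lipid handling (0.234) and ribosomal protein genes (0.167). It was negative for neurons (-0.989, lower in 22 of 24 genes), neutrophils (-1.77), Schwann cells (-0.584), interferon response (-0.53), endothelium (-0.508), astrocytes (-0.494), mature oligodendrocytes and myelin (-0.38), mitochondrially encoded genes (-0.373), mural cells (-0.321), cholesterol synthesis (-0.291), reactive astrocytes (-0.225), fibroblasts and meninges (-0.118) and oxidative phosphorylation (-0.116). With an estimated correlation and in fry, 0 of the 18 passed. As many lists came up in 2 of 100 splits of the libraries, and the highest other split gave 19 (median 8). The share is small, but list counts of several comparisons were split and no correction was made for this. Chance is therefore not excluded for the number of lists or for any list by itself. No splits were run with a library left out, and the number was 11 without exercise replicate 17 of day 10. Without it, the median difference was 0.294 for proliferation, 0.113 for glycolysis, 0.0338 for phagocytosis and lipid handling, 0.0529 for ribosomal protein genes, -0.148 for myelin and -0.0898 for reactive astrocytes, and it turned to 0.067 for fibroblasts and meninges. For genes, edgeR called 0 in the interaction (1376 at an unadjusted p under 0.05, 13 by DESeq2, 0 by limma-voom). All 100 of 100 splits give at least 0, so that this count cannot test chance (highest other 14), while 4 of 100 splits reached the 1376 (highest other 1518).

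The splits bear on the other results as follows. The 1858 genes between the days in control were reached by 1 of 35 splits, the real one, with 0 in the highest other, and the 1520 in exercise by 1 of 35, with 38 in the highest other, so that chance is excluded for both. The 22 genes of the exercise effect averaged over the days were reached by 1 of 100 splits, the real one, with 1 gene in the highest other. This argues against chance for that count with all libraries. It is the smallest share these splits can give, and counts of several comparisons were split without correction. As 0 genes passed without control replicate 5 of either day or exercise replicate 13 or 19 of day 10, chance is not excluded for single genes. Nor is chance excluded for the 29 genes at day 10, since 2 of 35 splits gave as many and 1 of them gave 47. The 0 genes by edgeR at day 5 (79 by DESeq2, 0 by limma-voom) cannot test chance, since 35 of 35 splits give at least 0 (highest other 1), while the 1513 genes at an unadjusted p under 0.05 were reached by 1 of 35 splits, the real one (highest other 1382). Chance is not excluded for the correlation of 0.0431 between the exercise effects of the days, where 23 of 100 splits gave as large a value and the highest other was 0.189. For lists, chance is not excluded at day 5 (3 lists; 33 of 35 splits, highest other 15), at day 10 (14; 4 of 35, 18), averaged (12; 16 of 100, 17), between days in control (13; 5 of 35, 13) or between days in exercise (13; 5 of 35, 15). Camera at its preset correlation called a median of 8.5 lists in the other splits of day 5, 9.5 in those of day 10 and 8 in those of the average.

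The endothelial list was lower with exercise at day 10, by a median of -0.60 in log2. The p with an estimated correlation was 0.000572 in the real split, reached by 1 of 35, and the smallest in another split was 0.0181. This excludes chance only for the list taken by itself: 1 of 35 is the smallest share these splits can give, and the list stood out among 30, of which about 1 would rank first in this way by chance. Over the 30 lists, its adjusted p with an estimated correlation was 0.0172. Exercise replicate 17 by itself is argued against, as 4 of 4 exercise libraries lay below the lowest control library. For a smaller amount of meningeal tissue, 2 exercise libraries, 18 and 19, lay inside the control range of the fibroblast and meninges list. They still lay below every control library for the endothelial list. This goes against that explanation only so far as the fibroblast and meninges list measures meninges. A list of leptomeningeal genes, tested below, was lower in 11 of 13 genes (median -0.423), so that the explanation stays open. After each library's trend with exon length was removed, the median was -0.591, which argues against that trend. A larger share of myeloid RNA, which would thin out the RNA of all other cells, stays open: the endothelial minus oligodendrocyte precursor level was -1.78 ± 0.0693 in control and -2.13 ± 0.217 in exercise (exact p 0.0571, n = 4). An effect of running on the vessels of the lesion, which the design names, may also be the cause and was not tested apart from the amount of vessel in the dissected pieces.

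Exercise replicate 17 at day 10 lay apart from its group. Its myelin level was 6.27, against 6.91 to 7.52 in the other exercise libraries of that day, and its proliferation level 4.72, against 3.5 to 4.2. Dixon's test flagged neither of these levels, and in this library it flagged only the glycolysis list. A library of day 5 under a day 10 label is argued against: along the axis of the genes called between the days in control it lay 41.4% of the way from the mean of the exercise libraries of day 5 to that of the other 3 exercise libraries of day 10, while the exercise libraries of day 5 lay between -10.5% and 10.7% and the other exercise libraries of day 10 between 85.8% and 108%. Low depth is argued against as well, since its total of 11.09 M lay inside the range of the other day 10 libraries. A lesion less advanced in its course, or dissected at another place, may differ in this way, and neither was tested. The homeostatic microglial list, whose level rose between the days, goes the other way from a less advanced lesion. Its level in replicate 17 was 8.06, against 7.27 to 7.84 in the other exercise libraries of day 10. Exercise replicate 17 also had the fewest detected genes of day 10, 18880 against 19266 to 19893 in the other libraries. Its sample quality weight in limma-voom, 0.448, was the lowest of the 16 libraries. The quality of the library was not tested and stays open. The authors' day 10 table leaves this library out.

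In the exercise effect averaged over the days, the called genes that were higher were longer than those that were lower, at a median of 7110 and 3530 nt. Over all genes tested, the effect had a Spearman correlation with exon length of 0.103, which 20 of 100 splits reached (highest other 0.146), so that chance is not excluded for the trend. Whether a trend with length between libraries is the whole cause of the calls stays open. With it removed, the called genes had a median absolute log2 change of 0.561, against 0.568 before, all 22 with the same sign, while 14 of them stayed past the threshold in a fit that called 18. With a trend in GC content removed, the median was 0.569, and 15 stayed among 16. The prediction had asked for 17 to stay before a trend was argued against, and neither fit reached this. Over the called genes as a set the folds were nearly unchanged, so that removing either trend changed the calls more than the folds. The folds of the genes whose calls ended were not looked at by themselves, and leaving out single libraries also ended calls. Other sources of a length difference, such as the condition of the RNA, were not tested and stay open.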

How the results depend on the processing

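DESeq2 on the 8 libraries of a contrast, DESeq2 on the 7 libraries of the authors' day 10 table, the fit without mt-Rnr2 and the neuron list as a covariate were chosen only after the result was seen. Over all alternatives, named genes kept their side of the threshold in 16488 cases, lost it in 693 and gained it in 273, and lists did so in 2156, 235 and 69; no direction reversed past a threshold. Where a count moved, the cause was not tested unless fewer libraries were fitted.

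Of the counts of genes, day 5 had 0 by edgeR (1513 at an unadjusted p under 0.05) under every scaling and filter, by limma-voom, in the 8 libraries alone and with the replicate block, and 79 by DESeq2, or 259 by DESeq2 on the 8 libraries. Leaving out 1 library gave 0 to 1, with 1 without exercise replicate 7. Day 10 had 29 genes, 25 to 38 under RLE and upper-quartile scaling, no filter, the non-robust fit, no mt-Rnr2 and limma-voom, 46 with at least 50 counts, 10 with the neuron covariate, 218 by DESeq2, 0 by edgeR in the 8 libraries alone, 177 by DESeq2 there and 174 in the 7 libraries of the authors' table. Leaving out 1 library gave 0 (control replicate 2 or 3, exercise replicate 17 or 19) to 133 (exercise replicate 18), with 2 without control replicate 5, 1 without exercise replicate 13 and 19 without control replicate 4.

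The averaged effect had 22 genes, 21 to 33 under the scalings, no filter, the non-robust fit, no mt-Rnr2 and the neuron covariate, 45 with at least 50 counts, 78 by limma-voom and 323 by DESeq2. Leaving out 1 library gave 0 (control replicate 5 of either day, exercise replicates 13 and 19 of day 10) to 100 (exercise replicate 18 of day 10). At day 5 it gave 11 without control replicate 1, 1 without control replicate 2, 9 without exercise replicate 1, 1 without exercise replicate 7 and 2 without exercise replicate 12. At day 10 it gave 4 without control replicate 2, 4 without control replicate 3 and 80 without exercise replicate 17. The interaction had 0 by edgeR (1376 at an unadjusted p under 0.05) and by limma-voom, 13 by DESeq2, and 0 to 1 with 1 library left out (1 without exercise replicate 1 of day 5).

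Between the days, control had 1858 genes, 1521 to 2571 elsewhere and 1301 to 1594 with 1 library left out, and 561 with the replicate block, which spends degrees of freedom on 2 shared numbers that do not pair the libraries. Exercise had 1520, 856 in the 8 libraries alone, and 975 (without exercise replicate 7 of day 5) to 1839 (without exercise replicate 17 of day 10). For exercise against control at day 10 and for exercise between the days, no paired analysis was possible because the groups share no replicate numbers.

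Counts of lists were 3 at day 5 (0 with an estimated correlation, 0 by fry, 2 to 5 with 1 library left out, with 2 without control replicate 6 and 5 without control replicate 5), 14 at day 10 (1, 1, and 11 to 17), 12 averaged (0, 2, and 6 without exercise replicate 17 of day 10 to 15 without control replicate 5 of day 10, with 7 without exercise replicate 12 of day 5), 18 in the interaction (0, 0, and 11 without exercise replicate 17 to 19), 13 between days in control (1, 9, and 13 throughout) and 13 in exercise (0, 11, and 11 to 16). The list at 1 for day 10 is endothelium, and that for control is proliferation. The correlation of the exercise effects between days was 0.0431, 0.0434 by RLE, 0.0675 with at least 50 counts, and -0.0312 (without exercise replicate 13 of day 10; -0.00493 without exercise replicate 1 of day 5) to 0.107 (without exercise replicate 17). Igf2 at day 10 kept a log2 change between -2.69 and -3.34 over all alternatives, with adjusted p-values between 7.59e-29 and 0.13. The depth of 8.13 to 13.93 M counts limits what can be said of genes of few counts such as Ppargc1a.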

Other observations

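No test of this part was chosen after its own result was seen, although both lists were written after Fkbp5 and Igf2 had been called at day 10.

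Fkbp5 was higher with exercise at day 10, and its induction by glucocorticoids made a broader rise of such genes a candidate explanation. The other 18 tested genes of a list of glucocorticoid-induced genes, of which Pdk4, Lcn2 and Dusp1 are also in fixed lists, had a median log2 change of -0.284 (12 lower and 6 higher; p 0.174 by camera with an estimated correlation). The rise that the hypothesis asks for was not seen, and with members going both ways (quartiles -0.594 and 0.216) the question stays open.

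Igf2 was lower with exercise at day 10, for which fewer leptomeningeal cells in the dissected pieces are a candidate explanation. The other 13 tested genes of a leptomeningeal list, of which Slc6a13 and Ogn are also in the fibroblast and meninges list, had a median log2 change of -0.423 (11 lower and 2 higher; quartiles -0.545 and -0.351; p 0.0954 by camera with an estimated correlation). The direction is that of fewer such cells, while the size is well short of the change of Igf2 (-3.04). The prediction counted a median above -0.5 against the explanation, and the median lay above it. The lower quartile, however, reached past -0.5. The members with the smallest p, Slc6a13 (-2.22) and Slc6a20a (-1.52), fell by more than the median, while 2 genes were higher. The test therefore cannot decide, and fewer such cells stay open as a cause, whole or in part.

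Ppargc1a, named in the study's title, had 4.31 ± 1.04 CPM in control and 7.59 ± 1.98 in exercise at day 5 and 9.99 ± 2.42 and 6.4 ± 2.07 at day 10 (SD, n = 4). These are values of whole dissected lesions and not of oligodendrocytes by themselves.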
